A study of Lobaria pulmonaria with 11 samples.

How the data were processed

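The series profiled thalli of the tree lungwort lichen Lobaria pulmonaria under ultraviolet-B (UV-B) lamps. A lichen thallus is a joint body of a fungus, the mycobiont, and photosynthetic partners. Here the partners are a green alga, the photobiont Symbiochloris reticulata, and a cyanobacterium, the cyanobiont Nostoc. Per the labels, dried and frozen thalli were rehydrated, kept wet in a climate chamber and irradiated at 3 W/m2 for 80 min per day, a daily dose of 14.4 kJ/m2, in a course planned for 14 days. Samples came from day 0 (3 libraries), day 2 (3), day 7 (2) and day 11 (3), at cumulative doses of 0, 28.8, 100.8 and 158.4 kJ/m2. Per the labels, polyadenylated RNA was selected and sequenced as directional single-end libraries.

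The deposited tables hold raw counts per library and transcript ID, with 1 table for the mycobiont and 1 for the photobiont. Their values are whole numbers with a different total in each library, and each replicate has its own column. A further table gives, per the file headers, the counts of reads before and after trimming and the reads mapped to each partner genome, beside the fraction of kept reads that each makes up. The submitters' processing notes name FastQC 0.11.8, Trimmomatic 0.39, HISAT2, HTSeq 0.5.4 and edgeR. The genome builds, the gene models, the strand setting of the counting and any filters are not given in the sources used here, so transcripts that overlap or share near-identical copies remain uncertain. The deposited fraction of cyanobiont reads differed from the deposited read count divided by the kept reads by over 0.0001 in 4 libraries, and shares were therefore computed from the read counts. Mapped and unmapped reads added up to the kept reads in all 11 libraries.

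The mycobiont table lists 15607 transcripts, of which 827 had no count in any library, and its totals ran from 8680745 to 17626099 counts per library. The photobiont table lists 12582 transcripts, of which 994 had no count, and its totals ran from 938418 to 2677845. The tables carry numeric transcript IDs that the files do not pair with gene names or functions. The lists of genes for DNA repair, antioxidants, chaperones, pigments, ribosomes, protein breakdown and photosynthesis fixed in advance could therefore not be matched, and no result by gene function is given. For each partner, 1 transcript that rose and 1 that fell are named by a fixed rule. Among transcripts called in the same direction on days 2, 7 and 11 against day 0, with a mean of 50 or more counts per library and every irradiated library on 1 side of all day 0 libraries, the rule takes the largest value of the smallest absolute log2 fold change. Where none qualified, day 11 alone was used.

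Changes were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, trimmed mean of M-values (TMM) normalization, the default expression filter by group). There was 1 fit per partner over all 11 libraries, so that all days shared 1 estimate of the spread. Each day was set against day 0, day 7 against day 2 and day 11 against day 7, and a test over the course took days 2, 7 and 11 against day 0 together. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The filter left 12089 mycobiont and 9862 photobiont transcripts. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. Levels are CPM, counts divided by the library total after TMM normalization, as edgeR gives them. The biological coefficient of variation was 0.401 in the mycobiont and 0.269 in the photobiont, and the median standard error of the log2 fold change of day 11 was 0.31 and 0.29.

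The procedure was tested on simulated counts drawn from 1 mean per transcript over all 11 libraries and the estimated dispersions. In these, 100 transcripts were changed 2-fold and 100 were changed 4-fold. In the mycobiont, 62% of the 4-fold changes were recovered for day 2 (11829 transcripts in that step), 45% for day 7 (11838) and 53% for day 11 (11822). The 2-fold changes were recovered at 8%, 1% and 5%. In the photobiont, 82%, 74% and 80% of the 4-fold and 22%, 16% and 25% of the 2-fold changes were recovered, over 9764, 9781 and 9791 transcripts. False calls made up 2.13% to 9.09% of the simulated calls.

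Shares of reads, the evenness of the counts and the number of transcripts detected at equal depth were compared between days by exact permutation tests over all 92400 assignments of the 11 libraries, with SciPy 1.17.1. The evenness was expressed as the effective number of transcripts, the exponential of the Shannon entropy of the count shares. Detection at equal depth is the number of transcripts expected in a random draw of 8680745 mycobiont or 938418 photobiont counts from each library. To compare partners, the mycobiont counts were also thinned to the photobiont total of the same library with 3 random seeds. Because days 2, 7 and 11 share their day 0 libraries, agreement between their fold changes is given beside 100 simulations of unchanged groups.

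The series describes the samples of a day as biological replicates. No pair of libraries from 1 day agreed within sampling noise: the mean chi-square per transcript, which is 1 for counting noise alone, was at least 55.7 in the mycobiont and 6.85 in the photobiont. The tests, the naming rule and most alternatives were set before the data were examined. The alternatives were median-of-ratios size factors, library totals without a composition factor, DESeq2 1.42.0, no filter and a stricter filter, a 2-fold minimum, adjusted p under 0.01, only the libraries of the days compared, the replicate number as a block, each library left out in turn and the thinned mycobiont counts. Apart from the photobiont share, the measures of the libraries, and the division of transcripts by their day 0 level, were chosen after the data had been seen. Settings that left out or modelled pairs of libraries with correlated deviations from their day means were added after the data had been seen.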

Results

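Gene expression of both eukaryotic partners of the lichen was followed in 11 libraries from thalli sampled before irradiation (day 0, 3 libraries) and after 2, 7 and 11 days of daily UV-B exposure (3, 2 and 3 libraries). The question was how the fungal mycobiont and the green-algal photobiont responded as the UV-B dose built up to 158.4 kJ/m2. After trimming, 15128362 to 29994464 reads were kept per library. The mycobiont received 8680745 to 17626099 counts per library and the photobiont 938418 to 2677845. The only unirradiated thalli were those of day 0, so that the UV-B dose and the time spent wet in the chamber cannot be told apart in any comparison with day 0. Among the irradiated days the cumulative dose rose in step with the day, so that dose and time cannot be told apart there either.

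The balance of RNA between the partners showed no detectable shift. The photobiont made up 12.2% ± 3.76 of the counts assigned to both partners at day 0 (SD, n = 3), 10.5% ± 2.35 at day 2 (n = 3), 11.8% ± 0.162 at day 7 (n = 2) and 10.5% ± 1.00 at day 11 (n = 3). No difference between the 4 days was detected by the exact permutation test (p = 0.816, and 0.816 after Benjamini-Hochberg adjustment over 11 measures of the libraries). Over the 11 libraries the photobiont share had no detectable correlation with the cumulative dose (Pearson r = -0.184, permutation p = 0.597, adjusted 0.597, and Spearman rho = -0.155, permutation p = 0.650, adjusted 0.650). The adjustment covers the 2 relations with dose computed over all 11 libraries. Without 2 of the 3 libraries farthest from the median dose, r lay between -0.183 and 0.00395. Reads of the cyanobiont made up 0.0159% to 0.223% of the kept reads, as 4759 to 35996 reads per library. Their mean was 0.113% ± 0.0718 at day 0 (SD, n = 3), 0.0631% ± 0.0564 at day 2, 0.167% ± 0.0791 at day 7 (n = 2) and 0.0417% ± 0.00958 at day 11 (exact permutation p = 0.274, adjusted 0.604). Selection of polyadenylated RNA excludes most bacterial transcripts, so these reads do not measure the amount of the cyanobiont.

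Measures of how widely the mycobiont counts were spread over transcripts had their highest means at day 0, without passing the adjusted test. The effective number of mycobiont transcripts was 4341 ± 228 at day 0 (SD, n = 3), 3225 ± 331 at day 2 (n = 3), 3541 ± 162 at day 7 (n = 2) and 3100 ± 393 at day 11 (n = 3). The exact permutation p over the 4 days was 0.0115, which did not pass the adjustment over 11 measures (adjusted p = 0.0907). At equal depth, 13533 ± 151 mycobiont transcripts were detected at day 0, against 13075 ± 49.9 at day 2, 13060 ± 124 at day 7 and 13027 ± 123 at day 11 (exact permutation p = 0.0165, adjusted 0.0907). The effective number of mycobiont transcripts was the other measure related to the dose. Its correlation over all 11 libraries is not given, because the day 0 libraries lie apart from the others. Within the 8 irradiated libraries none was detected (Pearson r = -0.143, permutation p = 0.730, adjusted 0.960; Spearman rho = -0.189, p = 0.704, adjusted 0.956; r between -0.624 and -0.0124 without 2 of the 3 day 2 libraries). This relation was computed after the data had been seen, with that of the photobiont share (Pearson r = 0.0233, adjusted permutation p = 0.960). Without 2 of the 3 day 2 libraries, r of the photobiont share lay between -0.862 and 0.298. The 10 most abundant mycobiont transcripts held 3.92% to 5.05% of the counts in the day 0 libraries and 5.30% to 9.82% in the others. In the photobiont the effective number of transcripts was 3967 ± 84.4 at day 0 and 4109 ± 355 at day 11, with no detectable difference between the 4 days (exact permutation p = 0.391, adjusted 0.676).

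**Figure D1:**
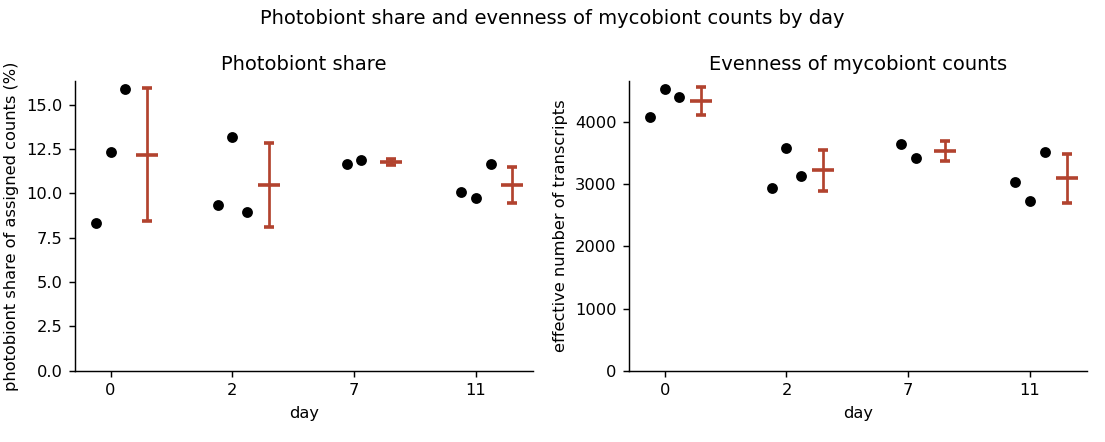
Photobiont share of assigned counts (left, in %) and effective number of mycobiont transcripts (right) against the sampling day, with 1 black point per library and the mean with its SD in red beside each day. The 3 day 0 libraries lie at 4088 or more effective mycobiont transcripts and the 8 irradiated libraries at 3655 or fewer.

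In the mycobiont, 1579 of 12089 tested transcripts (13.1%) changed by day 2, 1039 of them higher and 540 lower than at day 0. The median absolute log2 fold change of these transcripts was 1.13, and 572 were at least 2-fold higher and 384 at least 2-fold lower. When the tested transcripts were ordered by their mean level in the day 0 libraries and divided into 4 groups of equal size, 15.2% of the most abundant group were called higher and 3.71% lower, and 2.81% and 3.01% of the scarcest group. Of the 1039 transcripts that were higher at day 2, 701 (67.5%) were also called higher at day 11, where independent lists would share 158. The 2 comparisons share their day 0 libraries, which can raise the overlap by an amount that was not measured. In 100 simulations of unchanged groups almost no transcript is called, so their mean overlap of 0.01 is no measure of it. The split depends on the scaling: with library totals in place of TMM, the median log2 fold change of all transcripts was -0.45, and 2679 transcripts were called, of which 466 (17.4%) were higher in place of 65.8%. The count was 958, 593 and 713 without day 0 replicates 1, 2 and 3, and 668 without day 2 replicate 3.

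At day 7, 2116 mycobiont transcripts (17.5%) differed from day 0, of which 1166 were higher and 950 lower, with a median absolute log2 fold change of 1.48. Of these, 687 were at least 2-fold higher and 840 at least 2-fold lower. In the group most abundant at day 0, 13.4% were called higher and 8.97% lower, and in the scarcest group 4.63% and 4.60%. With library totals the median of all transcripts was -0.35, and 24.0% of 2229 calls were higher in place of 55.1%. Higher transcripts were fewer than lower ones without day 0 replicate 3 (637 of 1307), with the stricter filter (920 of 1889) and with only the libraries of the 2 days (825 of 1711). The count was 1141 and 1307 without day 0 replicates 2 and 3. It also fell without either day 7 library, or without day 2 replicate 2 and day 7 replicate 2 together, which leaves 1 library at day 7. That pair was picked after the data had been seen, as its deviations from the day means correlated at 0.386. With 2 libraries at day 7, the value for day 7 replicate 1 is -0.386 by construction, so neither day 7 library can be named as the odd one. A term common to the pair called 3 of 12089 transcripts.

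The number of mycobiont calls was highest at day 11, when 3504 transcripts (29.0%) differed from day 0, 1835 higher and 1669 lower. The changes included 920 transcripts at least 2-fold higher and 1312 at least 2-fold lower, and 940 that changed at least 4-fold. In the group most abundant at day 0, 23.1% were called higher and 11.9% lower, and in the scarcest group 7.01% and 11.6%; most transcripts of each group were not called. The median log2 fold change was 0.19 in the most abundant and -0.49 in the scarcest group, a gap of 0.68. With library totals these medians were -0.25 and -0.94, so the sign of the first depends on the scaling. With transcripts ordered by a single day 0 library that was left out of the fold change, the gap was 0.58 to 0.80. With library totals the median of all transcripts was -0.47, and 17.0% of 4256 calls were higher in place of 52.4%. Higher transcripts were fewer than lower ones without day 0 replicate 1 (1315 of 2670) or 3 (1145 of 2304), with the stricter filter (1439 of 2948) and with only the libraries of the 2 days (1602 of 3266). The count was 2255 and 2304 without day 0 replicates 2 and 3. It was 2338, 2636 and 2694 without day 11 replicates 1, 2 and 3. Each of these leaves 2 libraries at day 11, as at day 7, where 2116 were called.

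Over the whole course, 3287 mycobiont transcripts (27.2%) changed by the test that takes the 3 irradiated days together. Called against day 0 on all 3 days were 478 transcripts that were higher and 221 that were lower. Further transcripts were called only later: 553 were called higher and 617 lower on days 7 and 11 but not on day 2, and 577 were called higher and 690 lower on day 11 alone. Another 309 were called higher on day 2 alone, and 13 were called in opposite directions on different days. A call on 1 day and not on another does not show that the days differ. The count over the course was 1904 and 2118 without day 0 replicates 2 and 3.

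Transcript 1250288 had the largest rise in the mycobiont by the naming rule, out of 467 that qualified. It had 3 to 6 counts per library at day 0, or 0.331 CPM ± 0.0696 (SD, n = 3), and 85.2 CPM ± 73.5 at day 2 (n = 3), 21.2 ± 9.24 at day 7 (n = 2) and 42.8 ± 24.5 at day 11 (n = 3). Its log2 fold change against day 0 was 7.95 (SE 0.89, edgeR adjusted p = 0.00132) at day 2, 5.94 (SE 0.86, adjusted p = 0.00419) at day 7 and 6.96 (SE 0.86, adjusted p = 0.00117) at day 11. The low counts of day 0 make the size of this fold imprecise. Transcript 1090633 had the largest fall, out of 178 that qualified, from 14.2 CPM ± 8.40 at day 0 to 1.93 ± 0.551, 2.00 ± 1.07 and 2.21 ± 0.952 on days 2, 7 and 11. Its log2 fold change was -2.87 (SE 0.55, adjusted p = 0.0103), -2.82 (SE 0.65, adjusted p = 0.0175) and -2.68 (SE 0.55, adjusted p = 0.00711) in turn. The day 7 call of 1090633 was lost without day 7 replicate 2 (adjusted p = 0.124), within a range of 0.000135 to 0.145 over 20 alternatives.

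**Figure D2:**
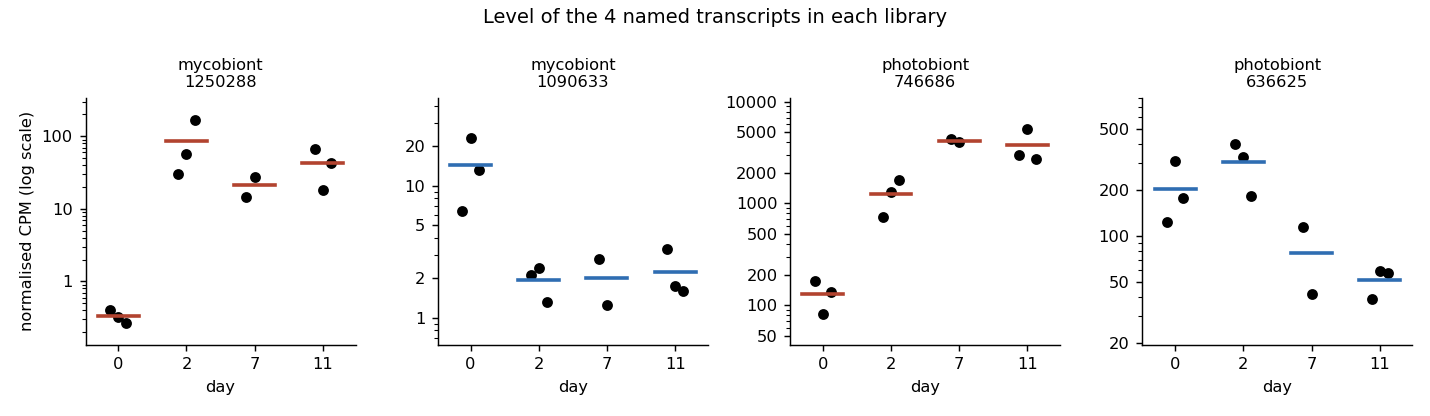
Normalised level of the 4 named transcripts in CPM, on a log axis that differs between panels, against the sampling day. Each point is 1 library and each line the mean of a day; mycobiont 1250288 lies below 1 CPM in the 3 day 0 libraries and above 10 CPM in all others, and photobiont 746686 goes from 130 CPM at day 0 to 4136 CPM at day 7.

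Few photobiont transcripts were called at first, and most calls were rises. At day 2, 9 of 9862 tested photobiont transcripts differed from day 0, all higher, and at day 7 there were 46 (0.466%), 45 of them higher and 1 lower. At day 11 there were 141 (1.43%), 109 higher and 32 lower, of which 105 were at least 2-fold higher and 30 at least 2-fold lower. Called higher on all 3 days were 5 transcripts, while 35 were called higher on days 7 and 11 but not on day 2 and 68 on day 11 alone. The test over the course called 137 transcripts (1.39%). DESeq2 called 78, 161 and 382 photobiont transcripts on days 2, 7 and 11, of which 59, 146 and 280 were higher and the others lower. It called 650 over the course. At an unadjusted p under 0.05 the edgeR test had 1038 (10.5%), 1039 (10.5%) and 1541 (15.6%) transcripts on the 3 days. No change would give a share of about 0.05.

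Photobiont libraries of day 0 replicate 3 and day 2 replicate 1 stood apart from the other 9: a term common to both, added after the data had been seen, called 746 transcripts, 338 higher and 408 lower in them. As the pair was picked from the same counts, these calls describe how it differed and do not test whether it stood apart. Without both libraries, 5, 30 and 98 photobiont transcripts were called on days 2, 7 and 11 and 63 over the course; with the common term there were 14, 41, 158 and 128. Single libraries also moved these counts. The day 2 count was 4, 29 and 5 without day 0 replicates 1, 2 and 3 and 3 without day 2 replicate 3. The day 7 count was 16, 13 and 27 without day 0 replicates 1, 2 and 3, and 23 and 22 without day 7 replicates 1 and 2. The day 11 count was 74, 35 and 54 without day 0 replicates 1, 2 and 3, 263 without day 2 replicate 1, and 26 and 55 without day 11 replicates 1 and 2. The count over the course was 85 and 69 without day 0 replicates 1 and 3, 63 and 214 without day 2 replicates 2 and 3, 90 without day 7 replicate 1, and 43 and 51 without day 11 replicates 1 and 2.

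Transcript 746686 had the largest rise in the photobiont, out of 5 that qualified. Its level was 130 CPM ± 45.1 at day 0 (SD, n = 3), 1236 ± 478 at day 2 (n = 3), 4136 ± 170 at day 7 (n = 2) and 3726 ± 1498 at day 11 (n = 3). The log2 fold change was 3.26 (SE 0.42, edgeR adjusted p = 0.00648) at day 2, 5.0 (SE 0.47, adjusted p = 0.000417) at day 7 and 4.85 (SE 0.45, adjusted p = 0.000191) at day 11. No photobiont transcript was called lower on all 3 days, and for day 11 alone the rule named transcript 636625 out of 18. It had 203 CPM ± 95.3 at day 0, 303 ± 111 at day 2, 77.9 ± 51.3 at day 7 and 51.7 ± 11.1 at day 11, a log2 fold change of -1.98 at day 11 (SE 0.44, adjusted p = 0.0483). That call was lost under 11 of 20 alternatives, with adjusted p from 0.000641 to 0.226. Among these, adjusted p was 0.153 and 0.121 without day 0 replicates 2 and 3, 0.0507 and 0.0711 without day 2 replicates 1 and 2, and 0.226, 0.134 and 0.104 without day 11 replicates 1, 2 and 3.

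**Figure D3:**
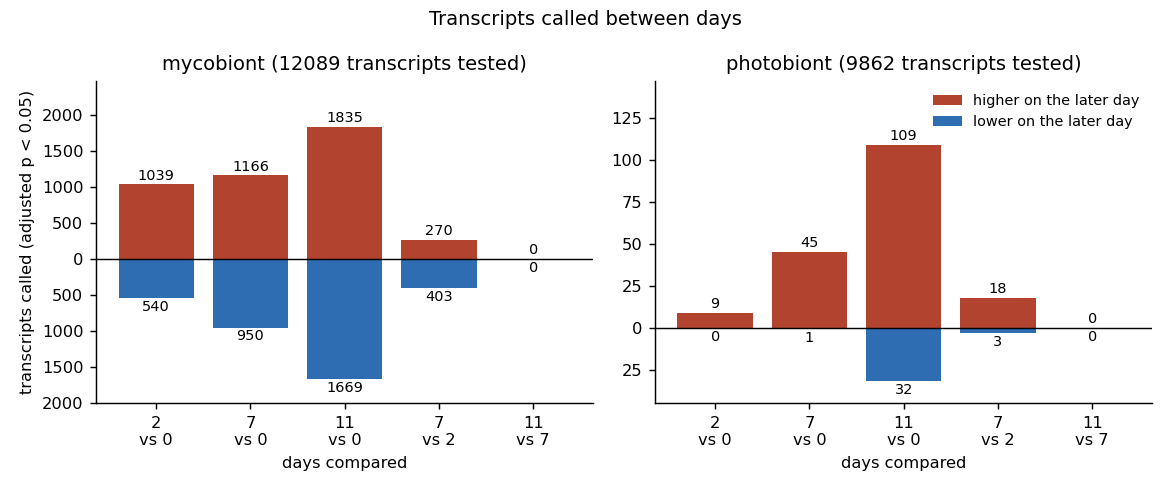
Number of transcripts called at an adjusted p under 0.05 by edgeR in each comparison of days, with transcripts higher on the later day above the line and lower ones below it, on a separate scale for each partner. With TMM the number of calls against day 0 rises from day 2 to day 11 in both partners. None is made between day 11 and day 7. Day 7 has 2 libraries and days 2 and 11 have 3, which bears on these numbers. With 1 library left out the photobiont count at day 11 is 26 to 263. With library totals in place of TMM the mycobiont count is 2679, 2229 and 4256 on days 2, 7 and 11. Most of those calls are lower, 17.0% being higher at day 11.

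Between successive days, 673 mycobiont transcripts differed between day 7 and day 2, 270 higher and 403 lower at day 7. Of the 270, 192 were called higher and 2 lower at day 11 than at day 0. Of the 403, 219 were called lower and 53 higher at day 11 than at day 0, and 139 had been called higher and 12 lower at day 2 than at day 0, in a comparison that shares the day 2 libraries. In the photobiont, 21 transcripts differed between day 7 and day 2, 18 higher and 3 lower. No transcript of either partner was called between day 11 and day 7 by edgeR, where the smallest adjusted p in the mycobiont was 0.0501. At an unadjusted p under 0.05 it had 622 mycobiont (5.15%) and 232 photobiont transcripts (2.35%), where no change would give a share of about 0.05. DESeq2 called 71 and 0. With library totals, 49.4% of 583 mycobiont calls between day 7 and day 2 were higher in place of 40.1%. The majority turned to higher without day 7 replicate 1 (138 of 219), without day 7 replicate 2 (90 of 127), without both day 2 replicate 2 and day 7 replicate 2 (59 of 95) and with only the libraries of the 2 days (58 of 113). The mycobiont count for day 7 against day 2 was 438 without day 0 replicate 1, 332 and 419 without day 2 replicates 1 and 3, 219 and 127 without day 7 replicates 1 and 2, and 95 without both day 2 replicate 2 and day 7 replicate 2. The photobiont count was 13 and 35 without day 0 replicates 1 and 2, 3, 0 and 45 without day 2 replicates 1, 2 and 3, 8 and 11 without day 7 replicates 1 and 2, 32 without day 11 replicate 3, and 7 without both photobiont libraries that stood apart.

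After each mycobiont library was thinned to the photobiont total, the mycobiont still showed more calls than the photobiont. There were 2082 to 2154 mycobiont transcripts called over the course, which is 22.0% to 22.8% of 9453 to 9460 tested, against 137 (1.39%) in the photobiont. For day 2, 917 to 973 mycobiont transcripts were called against 9, for day 7 1357 to 1388 against 46, and for day 11 2125 to 2177 against 141. The 4-fold changes simulated for the self-test were recovered more often in the photobiont (80% at day 11) than in the mycobiont (53%). That self-test changed 100 transcripts 2-fold and 100 4-fold, far fewer than were called in the mycobiont here. Its recoveries therefore need not hold for these data. Counts per transcript and the spread between replicates were not matched, and the difference between the partners was not itself tested, because transcripts are not replicates.

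**Figure D4:**
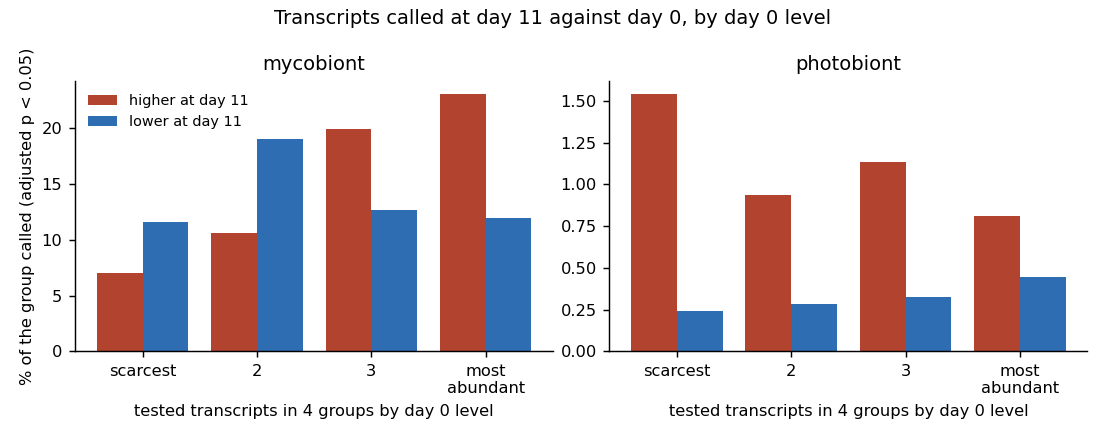
Share of transcripts called higher (red) or lower (blue) at day 11 against day 0, in % of each of 4 groups of equal size of the tested transcripts ordered by mean level in the day 0 libraries, on a separate scale for each partner. In the mycobiont the most abundant group has 23.1% higher and 11.9% lower and the scarcest 7.01% higher and 11.6% lower, with TMM scaling. Library totals shift the median of all mycobiont transcripts to -0.47 on the log2 scale. Fewer counts make scarce transcripts harder to call, so the shares do not compare how often the groups respond.

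The fold changes of days 7 and 11 correlated more closely with each other than with those of day 2, in both partners. Across 12089 mycobiont transcripts, which are not independent replicates, the Pearson r between the log2 fold changes of days 7 and 11 was 0.783, beside a mean of 0.421 in 100 simulations of unchanged groups with shared controls. It was 0.624 (simulated 0.427) for days 2 and 7 and 0.621 (simulated 0.489) for days 2 and 11. The covariance exceeded the simulated one by 1.43, 0.856 and 0.837 in the same order. On both days 7 and 11, 1033 mycobiont transcripts were called higher and 839 lower, where independent lists would share 177 and 131. Independent lists leave out the effect of the shared day 0 libraries. The simulated overlap of 0 and 0 follows from the lack of calls in unchanged groups. How much of the overlap of calls the shared controls bring was therefore not measured. In the photobiont, r was 0.787 for days 7 and 11 (simulated 0.421, covariance excess 0.268), and 40 transcripts were called higher on both days, where independent lists would share 0.497. The photobiont r was 0.396 for days 2 and 7 and 0.395 for days 2 and 11, below the simulated 0.431 and 0.489, with covariance excesses of 0.0516 and 0.0540. The 3 day 0 libraries cannot be split into groups of at least 2, so part of each excess may come from the shared controls. The fold changes of day 7 against day 2 and day 11 against day 7, which share the day 7 libraries with opposite sign, had r = -0.418 in the mycobiont (simulated -0.624) and -0.304 in the photobiont (simulated -0.614).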

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

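All settings below were set before the data were examined except those that leave out or model pairs of libraries and the orderings of transcripts by abundance. The numbers give mycobiont transcripts first where both partners appear. For the numbers of called transcripts and the correlations between days, 89 combinations of result and setting, apart from single libraries left out, stayed within 1.5 times or 1 SD and 53 did not. No named transcript changed direction on a day on which it was called. The cause of the shifts was not tested unless stated.

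DESeq2 called more: 2556 mycobiont transcripts for day 2 against day 0, 1664 for day 7 against day 2 and 71 for day 11 against day 7, and in the photobiont 650 over the course, 78, 161 and 382 for days 2, 7 and 11 and 182 for day 7 against day 2. Library totals gave 2679 for mycobiont day 2 and 1 for day 11 against day 7, where no filter and the stricter filter also gave 1. A minimum of 2-fold left 956 and 2232 mycobiont transcripts on days 2 and 11. An adjusted p under 0.01, stricter by construction, left 1194 over the course, 417, 587 and 1414 for days 2, 7 and 11 and 110 for day 7 against day 2 in the mycobiont, and 27, 3, 13, 27 and 0 in the photobiont. With only the libraries of the days compared, and so fewer samples, 113 mycobiont transcripts were called for day 7 against day 2, and 5, 245 and 7 photobiont transcripts for day 2, day 11 and day 7 against day 2. Thinned to the photobiont depth, the median mycobiont counts were 2129 over the course and 921, 1371 and 2140 for days 2, 7 and 11, a loss that thinning alone brings.

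The replicate block, with the number in the labels as a block, gave 1317 mycobiont transcripts for day 7, 263 for day 7 against day 2 and 1 for day 11 against day 7, and in the photobiont 39 over the course, 14 and 60 for days 7 and 11 and 1 for day 7 against day 2. It moved no other count by over 1.5 times. The labels do not say that the numbers pair the samples: deviations from the day means correlated between same-numbered libraries at -0.077 to 0.386 in the mycobiont and -0.218 to 0.345 in the photobiont, and between differently numbered libraries at -0.386 to 0.254 and -0.355 to 0.395.

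Without both day 2 replicate 2 and day 7 replicate 2, the mycobiont counts were 473 for day 7, 95 for day 7 against day 2 and 2 for day 11 against day 7, and a term common to both gave 2 for the last. Without both day 0 replicate 3 and day 2 replicate 1, the photobiont counts were 63 over the course, 5 and 30 for days 2 and 7 and 7 for day 7 against day 2, and a common term gave 14 for day 2. These were chosen after the data had been seen, and the first, like the omission of a single day 7 library, leaves 1 library at day 7, assumed to vary like the others.

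With each library left out in turn, the mycobiont counts ran from 1904 to 3023 over the course, 593 to 1518 for day 2, 585 to 2365 for day 7, 2255 to 3721 for day 11, 127 to 653 for day 7 against day 2 and 0 to 14 for day 11 against day 7. The photobiont counts ran from 43 to 214, 3 to 29, 13 to 66, 26 to 263, 0 to 45 and 0 to 3 in the same order. The exact permutation p of the photobiont share lay between 0.231 and 0.893 when each library was left out, and at 0.846 without the 10 most abundant transcripts and 0.849 from mapped reads. Without each day 0 library, r between fold changes was computed for days 2 and 7, 2 and 11, and 7 and 11. It lay at 0.629 to 0.643, 0.639 to 0.652 and 0.794 to 0.795 in the mycobiont. In the photobiont it lay at 0.409 to 0.521, 0.431 to 0.514 and 0.784 to 0.832. All mycobiont values lay above those with all libraries (0.624, 0.621 and 0.783). Fewer shared day 0 libraries can raise r, and no simulation with 2 of them was made. Over transcripts called over the course alone, r was 0.636, 0.595 and 0.912 in the mycobiont, in the same order of days. In the photobiont it was 0.338 for days 2 and 11 and 0.939 for days 7 and 11. These transcripts were picked by a test of the same fold changes, which can raise r by selection. No simulation was set beside these values.

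The tests of gene lists, with their alternatives, were not run because the IDs carry no names. The median count per tested transcript and library was 325 in the mycobiont and 78.1 in the photobiont, and thinning lowered the number of mycobiont calls. Ordered by the mean over all libraries, the gap between the mycobiont abundance groups at day 11 was 1.08 in place of 0.68, and by day 0 and day 11 with equal weight 1.05.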

Other observations

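The tests in this part were chosen only after the results they bear on had been seen.

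Few transcripts went from silence to clear expression with irradiation. In the mycobiont, 4, 2 and 7 transcripts had at most 3 counts over the day 0 libraries and at least 30 counts in every library of day 2, 7 or 11. The reverse, counted in every day 0 library and silent later, held for 0, 11 and 8. In the photobiont, 0, 2 and 2 transcripts appeared and none disappeared by the same criteria. These are raw counts not matched for depth, so 30 counts is a higher level in the photobiont, whose libraries hold fewer counts. Day 7 has 2 libraries in place of 3, which makes its criteria easier to meet.

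The log2 fold changes of mycobiont transcripts at day 11 were higher for the group most abundant at day 0 than for the scarcest of 4 equal groups; a scaling factor common to all transcripts leaves this gap as it is, but it can turn the sign of a group's median. Neither depth nor an ordering that includes the change accounts for all of it, since ordering by 1 day 0 library left out of the fold change, with all libraries at equal depth, still gave a gap of 0.53 to 0.76. A fault of library making that struck both partners' RNA at all levels could show in the photobiont, whose counts come from the same libraries. There the highest gap at day 11 was 0.008, with counts as deposited and the ordering library left out of the fold change. The day 0 levels spread less in the photobiont, with an SD of log2 CPM of 1.495 against 2.485 in the mycobiont. The photobiont therefore cannot exclude a fault that acts mainly on the scarcest transcripts. An even background of reads in the day 0 libraries, such as genomic DNA, may account for part of the gap, which went from 0.58 to 0.80 as counted to 0.51 to 0.75 with 0.0838 CPM taken off every day 0 value (the mean of the 1083 transcripts counted in no irradiated library) and to 0.31 to 0.56 with 0.354 CPM (the mean of the 256 of them counted at day 0); whether the other 827 can be counted at all is not known. Biases by transcript length or base composition were not tested, and neither UV-B nor the time since rehydration was tested as the origin, as day 0 holds the only unirradiated thalli.

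The photobiont profiles of day 0 replicate 3 and day 2 replicate 1 deviated from their days in the same direction (correlation of the deviations over transcripts 0.395). Depth does not account for it, since the correlation was 0.389 at equal depth. In the mycobiont counts of the same libraries, both of the 2 libraries correlated best with their own day. This argues against a wrong label of a whole library, but does not cover a mix-up confined to the photobiont counts. Of 39 photobiont transcripts with at most 3 counts in some libraries and at least 30 in all others, at equal depth, 32 (82.1%) separated one or both of these libraries from the rest. Both together were separated by 5, against 0 for any other pair of libraries. Day 0 replicate 3 alone was separated by 19 and day 2 replicate 1 alone by 8, so most of the 32 parted only 1 of the 2 libraries. A different algal genotype or mixture of strains in these 2 thalli, not necessarily the same in both, may give such values and may be tested on the reads.

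In the mycobiont, 111 transcripts were all or none by the same criteria, in 55 different sets of libraries. The most frequent set, day 2 replicate 3 with day 11 replicates 1 and 3, held 9 transcripts. A switch that follows the sampling day would give transcripts counted in all libraries of a day or in none, and 1 of the 111 was of that kind. Genetic differences between the sampled fungal thalli may give such sets; this was not tested, as no reads were used here.

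Regrouping the libraries bears on whether the numbers of calls could arise by chance. Over the course, 1 of 50 groupings of the 11 libraries into groups of the same sizes, the real one, reached the real number of calls in each partner. It called 3287 mycobiont transcripts against at most 16 in another grouping, and 137 photobiont transcripts against at most 29. With 50 groupings, 1 in 50 is the smallest share that could be found, so chance is made unlikely but is not excluded. Groupings that mix the days may also raise the spread, so their low counts do not measure how far the real count exceeds chance. For single days the 10 splits of 6 libraries are too few for a share under 0.05. There the real and the highest other number of calls were 1579 and 3 for mycobiont day 2, 3504 and 2 for mycobiont day 11, 9 and 0 for photobiont day 2 and 141 and 0 for photobiont day 11, with the real split the only 1 of its 10 to reach its number.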
